A study of Mus musculus with 4 samples.

How the data were processed

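RNA from mouse oocytes was amplified with Smart-Seq2 and sequenced on Illumina libraries, per the labels. The 4 libraries were grouped by their titles into 2 control and 2 mutant libraries, and replicate numbers were taken from the same titles. The authors deposited a matrix of whole-number counts per gene for the series and a table per library with expected counts, TPM, FPKM and lengths per gene. Per the submitters' processing notes the tools were cutadapt 1.16, STAR and RSEM and the genome build was mm10. Their roles, settings and the counter behind the matrix are not given in the sources used here. The deposited count matrix held whole numbers with no normalization. Per the file headers the tables per library have the form of RSEM gene results, in which an expected count divides reads that fit several genes between them. TPM and FPKM were deposited by the authors as well, per the file headers, of which TPM was compared for *Ezh2* and FPKM was not tested. The gene lengths and effective lengths were deposited by the authors in bases, per the file headers. No file held values per transcript. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, are uncertain.

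The matrix totals lay between 25090032 and 26617816 counts per library, from 1.06 to 1.076 times the RSEM totals. No row lacked a gene. Of 55335 gene IDs, 55154 matched GENCODE mouse release M21 without their version number, and its mm10 coordinates and gene types were used. Gene symbols were taken from the deposited tables per library. A gene at 0 in a group has a floor of 3 counts over the group, 0.0600 CPM in controls and 0.0548 CPM in mutants. Amplified reads are not independent molecules, so floors and intervals cover counting error only.

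The matrix counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest, genotype as the only term, Benjamini-Hochberg adjusted p under 0.05), which left 2 residual degrees of freedom. CPM values are on the TMM-scaled library sizes of the tested genes. The SE of a log2 fold change is its size divided by the square root of F. The fitted fold change of a gene at 0 in a group depends on the prior count, so a bound is given for it. The tested genes numbered 15493. The common biological coefficient of variation was 0.353. On simulated counts for this comparison with 50 genes changed at each size and 14805 genes tested, the test recovered 16% of 2-fold, 46% of 4-fold, 56% of 8-fold and 86% of 16-fold changes, with 6 calls among unchanged genes, and it made 0 calls when no gene was changed. Most 2-fold changes were therefore out of reach.

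The 21 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and with an estimated one, and adjusted across the lists. With the estimated correlation no list passed. The fry test passed for 0 lists for a balanced direction and for 16 lists for changes in either direction, which compares no list with other genes. Of 1074 names on the lists 8 matched no gene. The named genes were chosen by a rule: *Ezh2*, then the 12 largest changes in each direction among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 10 CPM, without predicted names, then up to 4 members per list with the smallest adjusted p, or the 2 most abundant members where none passed. *Suz12*, *Eed*, the nuclear copy genes and the marker genes of single libraries were added after their values were seen. The lists, the rule, the tests and most alternatives were chosen before the data were examined. A leukocyte list and a list of meiotic prophase genes were written after.

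The alternatives were DESeq2 1.42.0, limma trend, other scalings, other filters, a replicate block, each library left out in turn, the RSEM expected counts rounded to whole numbers, mitochondrial and ribosomal protein genes left out, and other thresholds. Group differences of library-level values were tested with two-sided exact permutation tests. Sequences of the nuclear copy were compared with the mitochondrial genes by BLAST 2.17.0, and positions and marker lists were tested by 10000 random placements or lists in Python 3.11.15 with NumPy 2.4.6, after checks on simulated positions and lists.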

Results

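The series measured RNA in mouse oocytes of the C57BL/6 strain by sequencing of Smart-Seq2 libraries, a method that amplifies full-length cDNA from very little RNA. It held 4 libraries, 2 labelled control and 2 labelled mutant. The mice carried a point mutation at the alternative splice site of *Ezh2* exon 3. *Ezh2* encodes the catalytic subunit of Polycomb repressive complex 2, which methylates lysine 27 of histone H3. The series describes mice with a long and with a short form, and the mutant label does not say which form these oocytes kept. The libraries held 26617816 and 25090032 counts in controls 1 and 2 and 26575938 and 26587327 counts in mutants 1 and 2, over 55335 annotated genes. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples.

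*Ezh2* (chromosome 6, 47530139 to 47595341, mm10) was read at 313 and 239 CPM (read counts scaled to the library size) in the control libraries and at 176 and 223 CPM in the mutant libraries. The means were 275.9 ± 51.9 CPM in controls and 199.5 ± 33.3 CPM in mutants (SD, n = 2 each). The log2 fold change was -0.47 (SE 0.20), and this difference did not pass the test (edgeR quasi-likelihood test, adjusted p = 0.219). In the deposited TPM values *Ezh2* was at 179 and 149.65 in controls 1 and 2 and at 122 and 151.38 in mutants 1 and 2. In TPM the groups thus overlapped, with mutant 2 above control 2. The deposited values are sums over each gene, so the share of the long and the short form could not be computed, and the level of *Ezh2* does not check the genotype labels.

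The comparison of mutant with control oocytes asked which transcripts differed between the groups. A difference may go with the *Ezh2* mutation or with genetic background, which these groups cannot tell apart. *Pnpla3*, which encodes a lipid droplet protein, rose 82.5-fold from 0.818 ± 0.246 to 67.7 ± 7.47 CPM (SD, n = 2 each; log2 fold change 6.36, SE 0.295, adjusted p = 0.000467). *Btla*, an inhibitory receptor gene of the immunoglobulin superfamily, rose 75.4-fold from 0.798 ± 0.274 to 60.2 ± 0.679 CPM, and the kinase gene *Stk32a* rose 52.0-fold to 44.6 ± 1.51 CPM. *Ucp2*, which encodes a mitochondrial inner membrane carrier, rose 61.5-fold to 17.2 ± 1.41 CPM. *Nox4*, an NADPH oxidase gene, reached 18.3 ± 0.0464 CPM against 2 counts in the controls, a ratio of 458 with a 95% counting interval of 127 to 3791.

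Among the other genes with the largest rises, several differed widely between the mutant libraries. *Stk17b* was at 0 in both controls and at 9.77 and 24.3 CPM in mutants 1 and 2, at least 280-fold higher. *H2-D1*, a class I histocompatibility gene with close paralogs, was at 0 in both controls and at 3.34 and 29.5 CPM in the mutants, at least 268-fold higher. *Cotl1*, an actin-binding protein gene, was at 5.04 and 31.6 CPM in the mutants, and the zinc finger gene *Zfp536* at 20.5 and 59.1 CPM. The vesicular glutamate transporter gene *Slc17a6* was at 17.4 and 11.4 CPM, and the protease gene *Prss23* at 18.1 and 3.08 CPM. The homeobox gene *Cphx1* was at 0 in both controls and at 35.6 and 38.1 CPM in the mutants, at least 614-fold higher. *Cphx1* belongs to a family of close copies, and with the RSEM counts its log2 fold change was 2.47 (adjusted p = 0.353), so its value is uncertain.

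Among the genes that fell, *Slc25a17*, a peroxisomal carrier gene, was the most abundant of the 12 largest, at 236.9 ± 49.0 CPM in controls and 5.03 ± 1.17 CPM in mutants (SD, n = 2 each; log2 fold change -5.55, SE 0.266, adjusted p = 0.000467). *Car8*, of the carbonic anhydrase family, fell 322-fold from 53.0 ± 17.8 to 0.163 ± 0.0710 CPM. *Arntl2*, a paralog of the circadian clock gene *Bmal1*, fell 38.7-fold, and the microtubule-associated protein gene *Map7* fell 20.2-fold from 65.2 ± 0.392 to 3.23 ± 0.207 CPM. *Sh3rf2* fell 193-fold, *Gulp1* 26.7-fold and *Cyp4a14* 19.4-fold. *Extl1* was at 16.7 ± 12.8 CPM in controls against 1 count in the mutants. *Vmn1r76*, a vomeronasal receptor gene with many close relatives, was at 51.9 ± 17.6 CPM in controls and at 0 in both mutants, at least 947-fold lower.

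In all, 581 of 15493 tested genes passed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 274 higher and 307 lower in the mutants. The control and mutant libraries did not overlap for any of the 581, and over all tested genes 54.6% did not overlap, where chance gives 33.3%. Of the genes that passed, 39 of the higher ones had 0 counts in both controls and 26 of the lower ones had 0 counts in both mutants. Protein-coding genes made up 211 of the higher and 215 of the lower genes, and 56 of the 581 were pseudogenes. With the RSEM counts 426 of the 581 passed in the same direction and 2 in the opposite one. Of the genes named here as changed, *Cphx1*, *Junb*, *Tubg1*, *Srsf6*, *Rad9a*, *Sesn1*, *mt-Nd3*, *mt-Nd4l*, *mt-Co3*, *Gm28438* and *Gm10222* did not pass with them, and *mt-Tr* and *Cyp4a14* were not tested with them. The count fell to 22 without control 1 and to 27 without control 2, and rose to 1688 without mutant 1 and to 1025 without mutant 2.

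**Figure D1:**
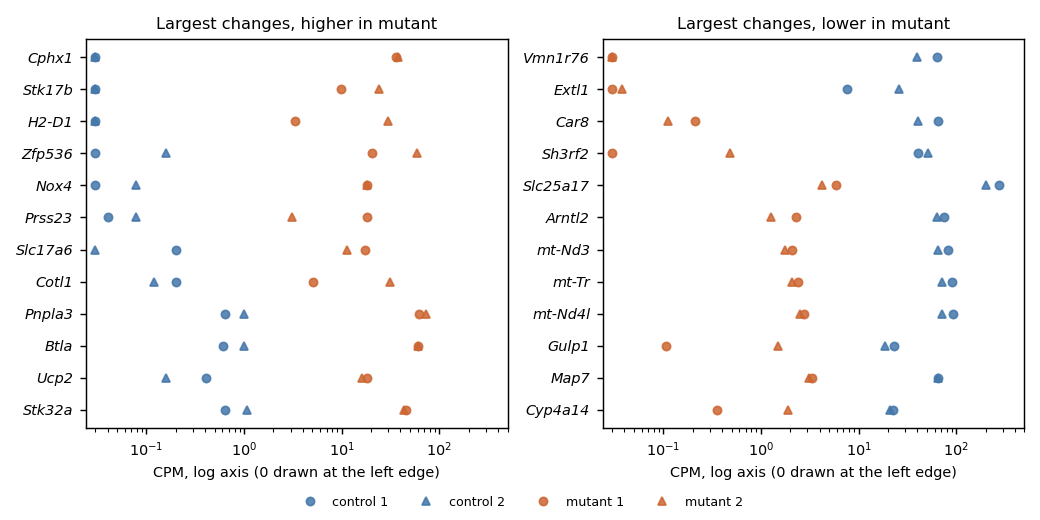
CPM on a log axis for the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in mutant oocytes, with 1 point for each library. Control points (blue) and mutant points (orange) do not overlap for any gene, while H2-D1 and Cotl1 differ widely between the mutant libraries.

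The genes of Polycomb repressive complex 2 showed no common shift. Of 13 measured members 1 fell and none rose over all genes, and 1 rose and 2 fell when adjusted over the list alone. The member that fell was *Aebp2*, an accessory subunit, from 180 ± 31.3 to 97.3 ± 0.00828 CPM (log2 fold change -0.89, SE 0.168, adjusted p = 0.0458). Its core partners *Suz12* (log2 fold change 0.28, adjusted p = 0.411) and *Eed* (-0.43, adjusted p = 0.137) did not pass. The list median was 0.15, its mean 0.01, and camera, a test of a list against the other genes, gave the direction down with an adjusted p of 0.923.

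Of 18 genes of the H3K27 demethylases and Polycomb repressive complex 1, *Pcgf3* rose 2.12-fold (log2 fold change 1.08), none fell, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.944). Of 47 other chromatin modifiers only *Ehmt2*, a histone H3 lysine 9 methyltransferase gene, rose, to 2.84 ± 1.20 CPM against 2 counts in the controls, and 1 rose adjusted over the list alone (camera adjusted p = 0.106). Of 135 developmental genes known as Polycomb targets in other cells, 33 were abundant enough to test. Of these, 0 passed the threshold over all genes or adjusted over the list alone (median -0.19, camera adjusted p = 0.923). The median was 0.34 without control 2 and 0.25 among genes with a mean of at least 10 CPM, and negative under the other alternatives, so its sign is uncertain. The fry test for changes in either direction gave this list an adjusted p of 0.00756, so smaller changes of single members are not excluded. *Gata3*, the most abundant of them, was at 99.3 and 95.7 CPM in controls and 112.9 ± 18.5 CPM in mutants, and *Tbx4* at 74.7 ± 19.2 and 65.6 ± 8.54 CPM (SD, n = 2 each).

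Genes imprinted through H3K27 methylation numbered 17 measured, of which 1 rose and 1 fell over all genes, and 5 rose and 1 fell adjusted over the list alone. The list had a median log2 fold change of 1.57, with 12 members positive and 5 negative, and did not pass camera (adjusted p = 0.106). With a library left out, the list had medians of 0.53 without mutant 1 and 2.03 without mutant 2. The list had medians of 1.38 without control 1 and 2.08 without control 2, so its size depended most on mutant 1. It passed camera with no filter on low counts (median 1.91, adjusted p = 0.0456) and with the replicate block (median 1.64, adjusted p = 0.028), and under no other alternative. *Xist*, the RNA that coats the inactive X chromosome, was at 2.98 and 4.40 CPM in the mutants against 1 count in the controls, a ratio of 184 with a 95% counting interval of 32.6 to 7286. Female somatic cells express *Xist*, and the mutant libraries also held markers of such cells. The cumulus gene *Gja1* was at 99.3 CPM in mutant 1 and the leukocyte gene *Ptprc* at 43.2 CPM in mutant 2. *Ptprc* was at 0 in both controls, but *Gja1* was at 10.9 CPM in control 1, which had 1 *Xist* count, and at 7.96 CPM in mutant 2. Whether *Xist* came from such cells was not tested. *Tox3*, a high mobility group box gene, fell 2.64-fold from 68.3 ± 9.89 to 26.0 ± 7.77 CPM. Among 28 genes with canonical imprints only *Zim1* fell, 28.3-fold from 4.14 ± 0.128 CPM, and 1 fell adjusted over the list alone (camera adjusted p = 0.791).

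Most oocyte genes did not pass the test. Of 64 maternal effect and oocyte genes only the homeobox gene *Obox2*, of a family of close paralogs, fell, 2.60-fold from 2242 ± 439.9 to 864 ± 69.5 CPM, and 1 fell adjusted over the list alone (camera adjusted p = 0.659). Of 89 meiosis and spindle genes, the tubulin genes *Tuba1b* and *Tubg1* rose 6.00-fold and 2.07-fold (*Tubg1* with an adjusted p of 0.0744 with the RSEM counts), and *Spc25*, a kinetochore gene, fell 2.45-fold; adjusted over the list alone, 1 rose (camera adjusted p = 0.659). *Tuba1b* shares most of its sequence with other tubulin genes. None of 61 genes of maternal mRNA translation and decay passed over all genes or adjusted over the list alone (camera adjusted p = 0.106). Their most abundant members, *Btg4* and *Dazl*, had log2 fold changes of -0.09 and -0.14.

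Of 12 genes of zygotic genome activation, the paralogs *Tcstv1* and *Tcstv3* fell 1.78-fold and 2.66-fold, and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.687). Of 68 splicing factors *Snrpb*, *Mbnl1* and *Srsf6* rose, *Snrpb* from 0.880 ± 0.179 to 9.56 ± 4.91 CPM and the others by 4.41-fold and 2.36-fold (*Srsf6* with an adjusted p of 0.0571 with the RSEM counts), and 3 rose adjusted over the list alone (camera adjusted p = 0.757). Of 47 DNA damage and apoptosis genes *Rad9a* and *Sesn1* rose (adjusted p = 0.0649 and 0.0585 with the RSEM counts) and *Casp8* fell 2.25-fold from 98.6 ± 16.6 CPM; the counts were 2 and 1 adjusted over the list alone as well (camera adjusted p = 0.422). None of 41 oxidative stress genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.106), and *Hsp90aa1* and *Prdx1* had log2 fold changes of -0.26 and -0.28. Of 14 immediate early genes *Klf6* rose 5.11-fold, and 6 rose and 1 fell adjusted over the list alone. The list had a median log2 fold change of 1.63 and did not pass camera (adjusted p = 0.106). It passed camera with the RSEM counts (median 2.23, adjusted p = 0.0173), with no filter on low counts (adjusted p = 0.0165) and with the replicate block (adjusted p = 0.0234). With a library left out, the list kept a positive median. This was 1.62 without mutant 1, 1.53 without mutant 2, 3.535 without control 1 and 2.34 without control 2. *Junb* fell 2.25-fold in the matrix, but with the RSEM counts its log2 fold change was 9.37 (adjusted p = 0.0537), so its direction is uncertain.

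The protein genes of the mitochondrial genome were lower as a list. All 13 had a negative log2 fold change, with a median of -0.82; 3 fell over all genes and 12 fell adjusted over the list alone. *mt-Nd3* fell 38.7-fold from 74.2 ± 11.8 to 1.91 ± 0.208 CPM and *mt-Nd4l* fell 30.9-fold from 81.9 ± 14.3 to 2.64 ± 0.179 CPM, both subunits of respiratory complex I. The transfer RNA gene *mt-Tr*, which lies between them, fell 35.8-fold, and *mt-Co3* fell 2.87-fold. The list passed camera (adjusted p = 5.02e-09) but not with an estimated correlation (adjusted p = 0.929 with an estimated correlation). The ribosomal RNA genes *mt-Rnr1* and *mt-Rnr2* did not pass (log2 fold changes 0.09 and -0.12, adjusted p = 0.877 and 0.813). Transfer RNA genes, chosen after their values were seen, went both ways. *mt-Ti* and *mt-Tt* had more counts in both mutants (log2 fold changes 1.36 and 0.88, adjusted p = 0.221 and 0.281). *mt-Tg*, which lies beside *mt-Nd3*, had 87 and 80 counts in the controls and 9 and 17 in the mutants. *mt-Te* had 840 and 466 counts in the controls and 327 and 365 in the mutants. In a near-identical nuclear copy on chromosome 1, the stretch that matches *mt-Nd3* and *mt-Nd4l* rose. *Gm28438*, the copy of *mt-Nd3*, was at 5.27 CPM in controls and 94.1 CPM in mutants, and *Gm10222*, the copy of *mt-Nd4l*, at 6.95 and 104 CPM. The other 5 genes of the copy did not pass, with log2 ratios of 0.65 for *Gm28437* and of -0.88, -0.63, -1.43 and -0.57 for *Gm10925*, *Gm28661*, *Gm28439* and *Gm29216*. Summed with their copies, *mt-Nd3* and *mt-Nd4l* each had a log2 ratio of 0.27, and *mt-Co3* with its copy *Gm28437* had -0.37. The size of the fall of these 3 genes may therefore depend on how reads were divided between the copies. With the RSEM counts *mt-Nd3* (log2 fold change -2.14, adjusted p = 0.0585) and *mt-Nd4l* (-1.43, adjusted p = 0.385) did not pass, nor did *mt-Co3* (-0.45, adjusted p = 0.152), *Gm28438* (5.16, adjusted p = 0.0531) and *Gm10222* (-0.16, adjusted p = 0.824).

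Ribosomal protein genes were higher as a list, with a median log2 fold change of 1.33 over 68 measured members and 62 of them positive, though none passed over all genes or adjusted over the list alone. *Rpl4* was at 128 ± 0.794 CPM in controls and at 277 and 174 CPM in mutants 1 and 2, while *Rpl17* was at 166.8 ± 9.78 CPM and at 149 and 108 CPM. The list passed camera (adjusted p = 5.14e-06), with an adjusted p = 0.929 with an estimated correlation. Its median against the controls was 1.29 in mutant 1 and 0.19 in mutant 2, and without mutant 1 it did not pass (median 0.35, adjusted p = 0.441). These genes have many processed copies in the genome. Markers of cumulus cells, which surround the oocyte, were also highest in mutant 1.

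Genes of lipid and glucose metabolism passed camera as well, with a median log2 fold change of 0.61 over 59 members (adjusted p = 0.0113, and adjusted p = 0.929 with an estimated correlation). Over all genes 2 rose and none fell, and adjusted over the list alone 15 rose and 6 fell. The fatty acid oxidation genes *Acadl* and *Acaa2* rose 4.16-fold and 7.25-fold, to 31.8 ± 8.54 and 6.73 ± 3.84 CPM. The list did not pass without mutant 1 (median 0.24, adjusted p = 0.397) or among genes with a mean of at least 10 CPM (median 0.26, adjusted p = 0.221). Of 64 nuclear genes of the respiratory chain *Cyc1* and *Uqcrc1* rose 10.4-fold and 26.1-fold, while *Sdhc* fell 2.82-fold from 45.1 ± 3.29 CPM, and the same counts, 2 and 1, held adjusted over the list alone (camera adjusted p = 0.111). The median of that list was 0.77 in mutant 1 and -0.16 in mutant 2.

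**Figure D2:**
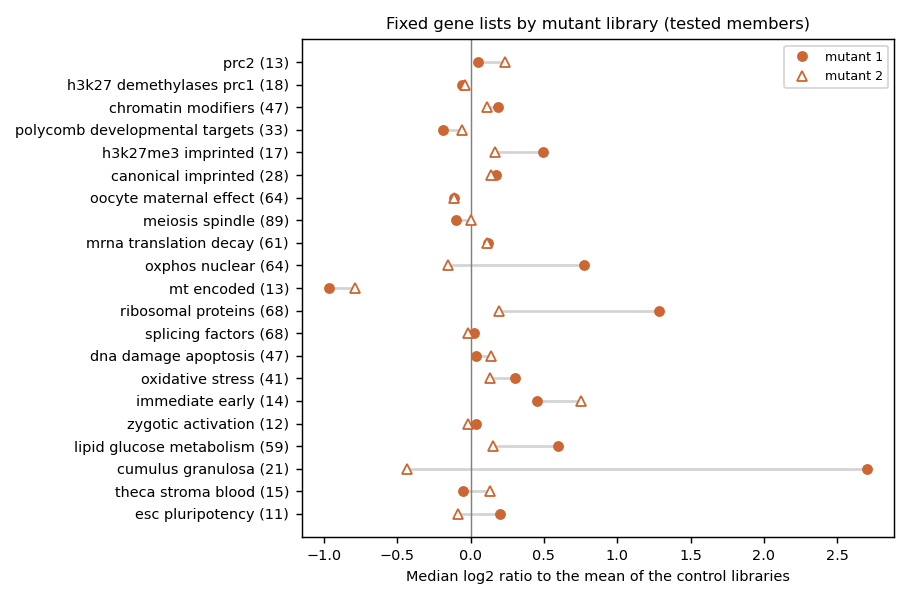
Median log2 ratio to the mean of the control libraries for each of the 21 gene lists, for mutant 1 (filled circles) and mutant 2 (open triangles), with the number of tested members in brackets. The mitochondrially encoded genes lie below 0 in both mutants, while the cumulus list lies at 2.71 in mutant 1 and at -0.43 in mutant 2.

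Markers of other cell types differed between the mutant libraries. Of 21 tested cumulus and granulosa genes only *Kitl*, which oocytes express as well, passed over all genes and adjusted over the list alone, and it fell 2.14-fold. The list, with a median log2 fold change of 2.71, did not pass camera (adjusted p = 0.111), but it passed without control 1 (median 7.08, adjusted p = 0.00112) and without mutant 2 (median 4.18, adjusted p = 2.75e-05), as with no filter on low counts (adjusted p = 0.0165) and with the replicate block (adjusted p = 2.14e-05), and without mutant 1 its median was -0.61 (adjusted p = 0.878). *Gja1*, the gap junction gene of cumulus cells, was at 99.3 CPM in mutant 1, 7.96 CPM in mutant 2, 10.9 CPM in control 1 and 0 in control 2. *Inhba* was at 86.7, 1.92, 8.98 and 0.2 CPM in the same libraries. Of 15 markers of theca, stroma and blood only *Lyz2*, a macrophage lysozyme gene, rose over all genes, 29.9-fold, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.923). The leukocyte genes *Ptprc* and *Coro1a*, chosen after their values were seen, were at 43.2 and 64.4 CPM in mutant 2, where *H2-D1*, *Stk17b* and *Cotl1* were also highest, and *Coro1a* was at 0 in the other libraries. None of 11 pluripotency genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.757), and *Dppa2* and *Trim71* had log2 fold changes of -0.09 and 0.15.

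**Figure D3:**
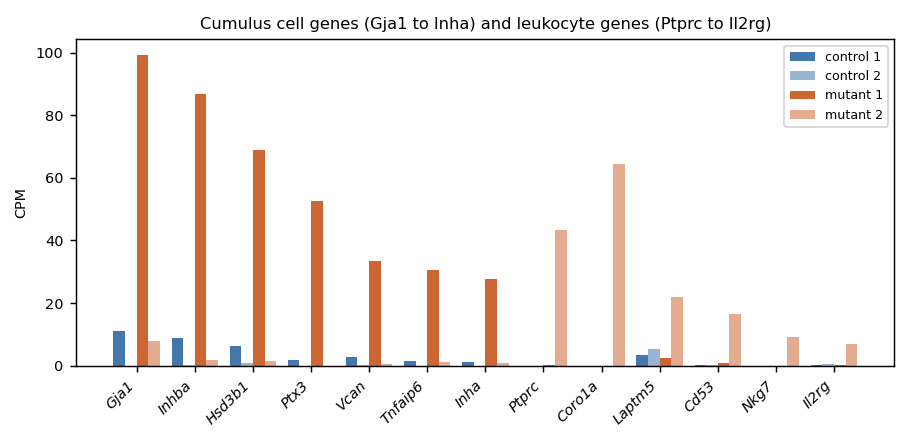
CPM of 7 cumulus cell genes (Gja1 to Inha) and 6 leukocyte genes (Ptprc to Il2rg) in each of the 4 libraries, with 1 bar per library. The cumulus genes are highest in mutant 1 and the leukocyte genes in mutant 2.

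More genes were detected in each mutant library than in either control library. Genes with at least 1 count numbered 20053 and 19948 in the controls and 21760 and 21485 in the mutants, a difference of 1622 between the means. After thinning to 25090032 counts in each library the difference was 1569.5. Of 44 cumulus genes, 20 and 8 had at least 10 counts in controls 1 and 2, and 35 and 17 in mutants 1 and 2. Of 30 leukocyte genes, on a list written after the data were seen, the numbers were 7, 6, 9 and 26. How far transcripts of other cells add to the detected genes was not tested. Mitochondrial genes took 2.75% and 2.14% of the counts in the controls and 1.83% in each mutant, and ribosomal protein genes took 0.095%, 0.086%, 0.238% and 0.092% in controls 1 and 2 and mutants 1 and 2. With 2 libraries against 2, the smallest p of a two-sided exact permutation test is 0.333, which the number of genes and the mitochondrial share reached.

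Across genes, Pearson's r of log2(CPM + 1) was 0.990 between the controls, 0.973 between the mutants and from 0.960 to 0.969 between a control and a mutant. Genes are not independent replicates, so these values describe the libraries only. As a check for a library deposited more than once, no pair agreed within sampling noise, with a chi-square of 32.1 per degree of freedom between the controls and 48.3 between the mutants.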

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

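A total of 7 genes outside the tested set had 0 counts in both control libraries and at least 10 in each mutant library. The counts summed over both mutants were 67 for *Armcx3*, 33 for *Arsa*, 74 for *Dsg2*, 20 for *Nhlrc3*, 45 for *Nnt* over its 2 gene IDs, 25 for *Rgs5* and 27 for *Tab1*. The filter on low counts left them out of the main fit. The alternative with no filter on low counts did test them, and its values for them are not given here. In the other direction *Msx2* and 3 genes with predicted names had 0 counts in both mutants and at least 10 in each control.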

How the results depend on the processing

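The 581 genes past the threshold (274 higher, 307 lower) are a count that moves with the processing, and the cause was not tested. DESeq2 called 1993 (1017 and 976), no filter on low counts 1322 (749 and 573), and an adjusted p under 0.1 gave 1721 (925 and 796). Library size alone gave 197 lower. Chosen after seeing the data, a test of protein-coding genes only called 349 (144 higher), and without mitochondrial, copy, cumulus and leukocyte genes 587 were called. The replicate block called 1213 (730 and 483) and 7 lists, but the numbers are not known to pair libraries, and the deviations of same-numbered libraries correlated at 0.166. Leaving out each library in turn gave 22 to 1688 genes, 10 to 962 higher and 12 to 726 lower, and the lone library of a group is then assumed to vary like the other group. The 3 lists past the threshold became 5 with library size alone, 7 with no filter, 1 without mitochondrial and ribosomal protein genes, and 2 to 6 with a library left out. With the RSEM counts 4 lists passed, the immediate early genes being the one added. Library size alone added the chromatin modifiers and the mRNA translation and decay genes. No filter added the H3K27-imprinted, nuclear respiratory chain, immediate early and cumulus lists. The replicate block added the H3K27-imprinted, oxidative stress, immediate early and cumulus lists. The difference in detected genes of 1622 was 1317.5 at 10 counts and 1089.5 at 1 CPM. *Ezh2* did not pass under any alternative, with log2 fold changes from -0.70 to -0.27. Of 841 values of named genes under the alternatives, 706 kept their direction and side of the threshold. Most of the others came from the fits without control 1 or without control 2, in each of which most named genes lost the threshold. Signs turned for *Junb* (9.37 with RSEM counts), for *Btg4*, which had not passed (0.00 with library size alone), and, with a library left out, for genes that had not passed: *Btg4* (-0.296 to 0.069), *Dazl* (-0.362 to 0.055), *Tbx4* (-0.438 to 0.053) and *Trim71* (-0.045 to 0.295). Depth limits what can be said of genes near the floor of 3 counts.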

Other observations

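Among the called genes not yet described, chosen after their values were seen from the 10 most abundant in each direction, *Mtfr2*, a mitochondrial fission regulator gene, rose 7.78-fold from 138 ± 22.1 to 1075 ± 226 CPM (SD, n = 2 each), and the glucosylceramide synthase gene *Ugcg* rose 8.37-fold to 776 ± 198 CPM. *Mmadhc*, a gene of cobalamin metabolism, rose 4.57-fold, and *Gli3*, a transcription factor of Hedgehog signalling, rose 3.10-fold. *Ypel5* fell 2.35-fold from 2297 ± 374 CPM, and the chromatin remodeller gene *Smarca2* fell from 583 ± 84.8 to 291 ± 31.8 CPM. *Klf17* rose 2.15-fold in the matrix but had a log2 fold change of -1.47 with the RSEM counts (adjusted p = 0.0113), so its direction is uncertain.

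All tests in this part were chosen after the results they concern were seen. Of 39 measured meiotic prophase genes, a list written because some had been seen among the called genes, 4 fell (*Dmc1*, *Tex12*, *Shoc1* and *Sycp1*) and 0 rose. Random lists matched on expression held 1.56 called genes on average (permutation p = 0.0679 over 10000 lists), so a shift of the group was not shown, and the list's origin favours a low p.

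*mt-Nd3*, *mt-Tr* and *mt-Nd4l* fell more than any other mitochondrial gene named here. The other 11 mitochondrially encoded protein genes had a median log2 fold change of -0.78 and a lowest value of -1.52, which argues against less mitochondrial RNA of all kinds as the whole cause. Reads shared with the nuclear copy on chromosome 1 (*Gm28438*, 24612775 to 24613119) may account for the fall of *mt-Nd3* and *mt-Nd4l*. The sum of each with its copy had a log2 ratio of 0.27. For *mt-Co3* and *Gm28437* the summed log2 ratio was -0.37, against -1.52 for *mt-Co3* alone. The other pairs had summed log2 ratios from -0.88 to -0.05. The copy differed from *mt-Nd3* by 1 mismatch over 345 bases and from *mt-Nd4l* by 0 over 294 bases, so what moved the reads from one to the other in the mutants, such as a variant of the mitochondrial genome, stays open without the reads. The lower median of the other genes stays open as well.

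Called genes lay next to each other on the chromosomes, in 71 neighbouring pairs against 21.4 expected at random (permutation p = 0.0001, the smallest that 10000 placements can give). The densest of 763 windows of 20 neighbouring tested genes lay on chromosome 1 from 65282056 to 71653200. It held 10 called genes, 4 higher and 6 lower, among them *Acadl* and *Rpe*, and the next windows held 7, 7 and 5. *Arntl2* lay in a window with 7 called genes, *Map7* and *Mtfr2* in 1 with 5, *Zim1* in another with 5, and *Btla* and *Extl1* in windows with 4. Without overlapping, non-coding and like-named genes, and with genes called in both count sources, 12 pairs remained against 6.3 expected (ratio 1.89, permutation p = 0.0253), too few to exclude shared reads. Of these 12 pairs 6 shared their direction, or 50% (95% Clopper-Pearson interval 21.1% to 78.9%), so a domain-wide change in 1 direction stays open, as it would give 73.9% if it made all pairs beyond the expected number, and the direction within the 71 pairs was not tested. Blocks of a different genetic background in the mutants could also give such pairs, but background and genotype cannot be told apart with these groups. Whether the named genes, in these windows or outside them, changed with the mutation or with background therefore stays open.

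Transcripts of other cells may have entered single mutant libraries. Of 44 cumulus markers 81.8% were highest in mutant 1, against 30.5% in random lists matched on the control level. For 79 ribosomal protein genes the share was 94.9%, against 36.0%. Of 15 leukocyte genes whose values had not been looked at when the list was written, 93.3% were highest in mutant 2, against 17.9%. The permutation p was 0.0001 for each, the smallest that 10000 lists can give. The random lists and the intervals below take genes as independent. Genes of a list moved together, with an estimated correlation of 0.90 for ribosomal protein genes and 0.56 for cumulus genes. These p-values and intervals therefore overstate the certainty and describe genes within single libraries only. A change shared by both mutants stays open: of the 36 cumulus markers highest in mutant 1, 13.9% were above both controls in mutant 2 (95% Clopper-Pearson interval 4.7% to 29.5%; 33.3% by chance), but control 1 also held such transcripts, and 19.4% were above control 1 and 50% above control 2 (interval 32.9% to 67.1%), while 35.7% of 14 leukocyte genes were above both controls in mutant 1 (interval 12.8% to 64.9%). Cumulus cells in mutant 1 and leukocytes in mutant 2 are candidate sources, though 20 and 8 of 44 cumulus genes and 7 and 6 of all 30 leukocyte genes had at least 10 counts in controls 1 and 2. Whether *Xist* came from such cells was not tested, and the shift to mutant 1 was not limited to cumulus genes (88.5% of 78 nuclear oxidative phosphorylation genes and 57.4% of 61 lipid and glucose genes were highest there, and 54.4% of ribosomal protein genes were above both controls in both mutants), which stays open.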
